A study of Mus musculus with 6 samples.

How the data were processed

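Total RNA of primary mouse cardiac fibroblasts was taken after treatment with saline or PDGF-DD, the dose of which the labels give as 20 µM (very high for a growth factor, so the unit is doubtful), and 6 messenger RNA libraries (3 per group) were sequenced as DNA nanoballs. Per the labels' protocols, messenger RNA was captured on oligo(dT) beads, fragmented and reverse transcribed with random hexamers. Per the submitters' processing notes, which give names without roles, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 were used and the genome build was mm9. The annotation, read filters and strand setting are not given in the sources used here, so reads of overlapping or antisense genes, and of genes with near-identical copies such as the histone genes, Hmga1 and Lyz2, may be shared between them and those values are uncertain. The authors deposited 1 table per library with 18059 genes. Its read count column holds estimated counts, which the authors made per gene and library without normalization, per the file headers and values, and between 31.9% and 32.6% of them are not whole numbers. The deposited FPKM values are fragments per kilobase of transcript, scaled by the authors to the depth of the library, and the deposited TPM values are scaled by the authors to the same sum in each library, per the file headers.

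The estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr at its defaults, which left 13270, libraries were scaled with TMM factors (between 0.995 and 1.01), and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 with robust estimation, two-sided, in R 4.3.3. Called genes have a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F, and 95% intervals use the total degrees of freedom of the test. Group values are means ± SD of CPM, the count scaled to the library size with TMM factors, over 3 libraries. Depth between 21221114 and 21371829 counts per library limits precision little for genes above a few CPM; for Pdgfd the values rest on 69 to 118 counts per library.

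A total of 35 gene lists were written before the data were examined, of which 32 had at least 5 tested members. Each was tested with camera in limma 3.58.1 on log2 CPM values (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether the genes of a list stand apart from all other genes. With that preset 7 lists were higher and 8 lower, and none of these calls held when the correlation was estimated from the 6 libraries. For each of these lists that setting gave the highest adjusted p of all alternatives tried. Counts of members that rose or fell use the adjusted p over all tested genes, and counts adjusted over the list alone adjust the same p-values within the list. Older symbols were matched to the files through a RefSeq gene table of assembly GRCm38.p6. Because that build differs from the one named by the submitters, no coordinates are given.

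The genes named were chosen by a rule written before the data were examined: all members of the PDGF and uPA list; the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups; the 5 rises and 5 falls with the smallest p; and from each list up to 4 called members with the smallest p and the 2 most abundant members. Not all genes that the rule allows are named, and some genes are not reported here by name but count in the tests of the lists. Genes outside it are said to have been chosen after their values were seen. The method was tested on simulated data for this comparison, drawn from the means and library sizes of the real libraries, in which 13175 genes were tested. Genes changed 1.15-fold were recovered in 28% of cases (14 of 50) and 1.3-fold in 66% (33 of 50). Those changed 1.5-fold were recovered in 82% (41 of 50) and 2-fold in 93.9% (46 of 49). Of 12976 unchanged genes 13 were called. Set against the few recovered genes, the share of false calls among all calls in this simulated set was above the adjusted p threshold used for calls. A far smaller share of genes was changed in this set than the 36.5% called in the real data. Benjamini-Hochberg adjustment depends on that share, so the rates of recovery and of false calls need not hold for the real comparison. In a second simulated set, with 13162 tested genes, camera found 20 of 20 lists changed 1.2-fold and 0 of 200 unchanged lists. Genes were drawn independently of each other there, whereas the correlation estimated in the real lists reached 0.271 for the ERK list. These numbers therefore do not give the rate of false list calls in the real data.

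Libraries were compared by Pearson correlation of log2 CPM across genes, by principal components of the 500 most variable genes and by a chi-square of counts over genes with a summed count of at least 20 in a pair. Correlations were between 0.993 and 0.995 within groups and between 0.988 and 0.989 across groups. The first component held 47.4% of the variance. No pair of libraries agreed within sampling noise, so each library counted as 1 replicate. The alternatives tried were size factors, upper-quartile factors and total counts in place of TMM, no filter and a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1, the replicate number as a block, a log2 fold change of at least 1, leaving out each library, and for the lists an estimated correlation and the rotation test fry. Transcript length and GC content for 1 check came from the GENCODE transcripts of GRCm38. TPM values were used only to check the files.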

Results

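The data are gene expression profiles of primary cardiac fibroblasts, the matrix-producing connective tissue cells of the heart, from young C57BL/6 mice. Cells isolated at 1 to 2 weeks of age and grown in medium with 15% serum received saline (control) or PDGF-DD for 12 hours, with 3 libraries in each group. PDGF-DD is the active dimer of platelet-derived growth factor D, a secreted growth factor that signals mainly through the receptor PDGFRβ. It is secreted in a latent form that proteases such as the urokinase plasminogen activator (uPA) cut to activate it. The series title places the experiment in a study of PDGF-D activation by macrophage-derived uPA and of angiotensin-driven cardiac remodelling in obese mice. The libraries were of nearly equal depth. The control libraries held 21258480, 21302214 and 21265584 estimated read counts and the PDGF-DD libraries 21221114, 21371829 and 21359757, with between 15880 and 16026 genes detected in each. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. That spread was small, with a common biological coefficient of variation of 3.96%.

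The labels disagree on genotype. The protocols describe all cells as coming from global PDGF-D knockout mice, while the genotype field names the control samples as control and the PDGF-DD samples as PDGF-D knockout. If the genotype field is right, genotype and treatment differ together between the groups. Reads assigned to Pdgfd (Entrez gene 71785) were present in all 6 libraries. The counts were 118, 114 and 91 in the control libraries and 69, 72 and 82 in the PDGF-DD libraries. This corresponds to 5.08 ± 0.68 CPM in control and 3.47 ± 0.31 CPM with PDGF-DD (SD, n = 3 each), a log2 fold change of -0.55 (SE 0.14, edgeR adjusted p = 0.00245). The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries can give. A count over the whole gene does not show which exons the reads came from, so it does not check whether the edited part of the gene was lost in either group. The groups below are those of the sample titles.

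Expression differed broadly between the groups. Of 13270 genes tested, 2535 were higher and 2310 lower with PDGF-DD than in control (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median absolute log2 fold change of these genes was 0.28, and 54 rose and 108 fell at least 2-fold. Rises and falls were ranked among called genes with a mean of at least 5 CPM and no overlap between the groups, since some genes with lower levels changed more. The largest rise in this ranking was that of Fosl1, a subunit of the AP-1 transcription factor, from 9.32 ± 1.97 to 38.4 ± 1.82 CPM (log2 fold change 2.04, SE 0.11, edgeR adjusted p = 1.07e-08). Lgr6, a receptor for R-spondins, rose from 4.72 ± 0.24 to 17.1 ± 0.31 CPM, and the chromatin protein gene Hmga2 rose 3.37-fold. Ptgs2, which encodes cyclooxygenase 2, rose 2.81-fold, and Errfi1, a feedback inhibitor of the EGF receptor, rose 2.62-fold. Sprr1a, Egr2, Prkg2, Ubash3b, Dkk2, Rgs16 and Esm1 also belonged to the 12 largest rises in this ranking, with log2 fold changes between 1.28 for Esm1 and 1.59 for Egr2. Among the rises with the smallest p-values was also Hmga1, a chromatin protein gene related to Hmga2, which rose 2.34-fold, a value that is uncertain because the gene has near-identical copies.

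The largest fall in the same ranking was that of Pdlim3, an actin-associated protein of muscle Z-discs, from 69.2 ± 3.02 to 13.6 ± 1.06 CPM (log2 fold change -2.35, SE 0.06, edgeR adjusted p = 1.64e-19). Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, was 2.74-fold lower, Tbxa2r, the thromboxane A2 receptor, 2.85-fold lower and the Notch target Heyl 2.62-fold lower. Dhrs3, a retinal reductase, fell from 134 ± 6.41 to 44.6 ± 3.69 CPM, and Ism1 fell from 12.5 ± 2.14 to 3.24 ± 0.40 CPM. The sodium channel gene Scn7a, the microtubule-associated protein gene Map2, the phosphatase gene Ptprz1, Adamtsl2, Map3k7cl and Rtn1 made up the rest of its 12 largest falls, with log2 fold changes between -1.49 for Ptprz1 and -1.27 for Rtn1. Among the falls with the smallest p-values were also Ccn5, a matricellular protein, from 770.0 ± 12.6 to 350.4 ± 20.5 CPM, and the potassium channel subunit Kcne4, from 123 ± 1.58 to 51.1 ± 3.35 CPM. Control replicate 1 stood somewhat apart from the other control libraries, with a chi-square per degree of freedom of 5.11 and 5.71 against them, compared with 2.48 between those 2 and 1.90 to 2.74 within the PDGF-DD group. Without it, 2643 genes were higher and 2374 lower.

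**Figure D1:**
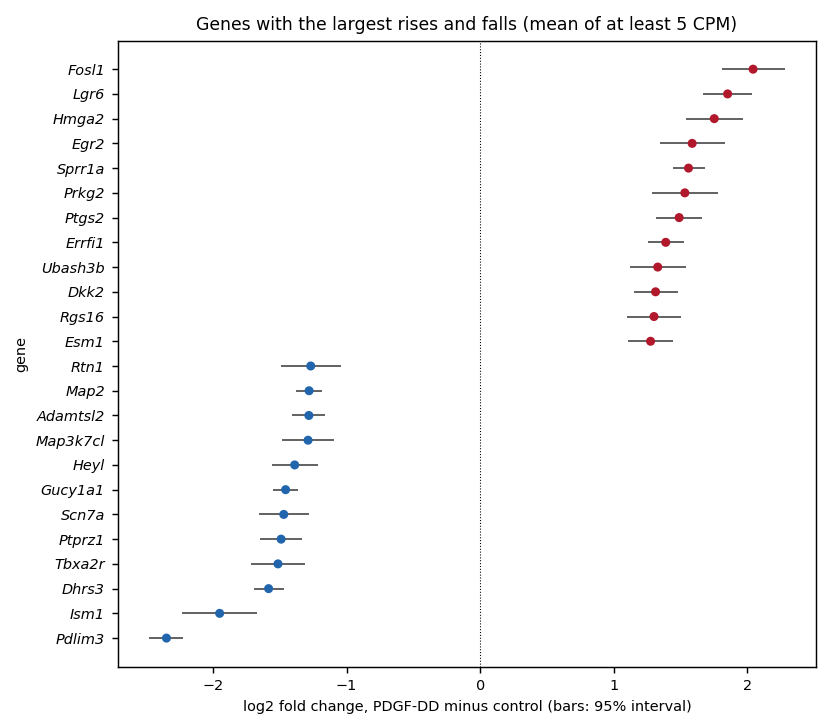
Log2 fold change (horizontal axis, PDGF-DD minus control) of the 12 genes with the largest rises (red) and the 12 with the largest falls (blue) among called genes with a mean of at least 5 CPM and no overlap between the groups. Dots are edgeR estimates from 3 libraries per group and bars are 95% intervals. Fosl1 lies at 2.04 and Pdlim3 at -2.35, and no interval reaches 0.

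The receptors for PDGF moved in opposite directions. Pdgfrb (Entrez gene 18596), which encodes PDGFRβ, fell from 821 ± 38.7 to 624 ± 18.1 CPM (log2 fold change -0.40, SE 0.04, edgeR adjusted p = 1.38e-08). Pdgfra (Entrez gene 18595), which encodes PDGFRα, rose from 135 ± 7.56 to 178 ± 3.68 CPM (log2 fold change 0.40, SE 0.04, edgeR adjusted p = 3.78e-08), and Nrp1, a co-receptor, rose by a log2 fold change of 0.43. Plaur (Entrez gene 18793), the receptor for uPA, rose from 39.8 ± 0.58 to 61.7 ± 1.06 CPM (log2 fold change 0.63, edgeR adjusted p = 1.04e-10).

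Transcripts of uPA itself (Plau) stood at 31.9 ± 1.55 CPM in control and 33.8 ± 0.67 CPM with PDGF-DD and did not pass the test (edgeR adjusted p = 0.283). Plat, the tissue-type activator, rose slightly from 88.6 ± 0.32 to 97.6 ± 2.16 CPM. Pdgfa rose by a log2 fold change of 0.15 (edgeR adjusted p = 0.0255), a call that was lost under upper-quartile scaling (adjusted p = 0.0537), in DESeq2 (0.0659) and without control replicate 1 (0.0796), control replicate 2 (0.1) or PDGF-DD replicate 3 (0.129), the lowest value under any alternative being 0.00589. The other ligands Pdgfb and Pdgfc, the receptor-like gene Pdgfrl and the protease inhibitor Serpine2 did not pass, with log2 fold changes between -0.16 and 0.13, except that Pdgfb passed as lower without control replicate 2 (adjusted p = 0.0361, and up to 0.367 under the other alternatives). In this list of 13 tested genes, 6 rose, 2 fell and 5 did not pass, with the same numbers adjusted over the list alone, and the list did not stand apart from the other genes (camera adjusted p = 0.141, and adjusted p = 0.274 with an estimated correlation). The rotation test fry asks instead whether the genes of a list move one way on balance, without comparing them with other genes. By fry the list was higher (adjusted p = 0.000386), and below the fry result is given for each list that did not stand apart by camera. Plasminogen (Plg) was among the genes too low to test.

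**Figure D2:**
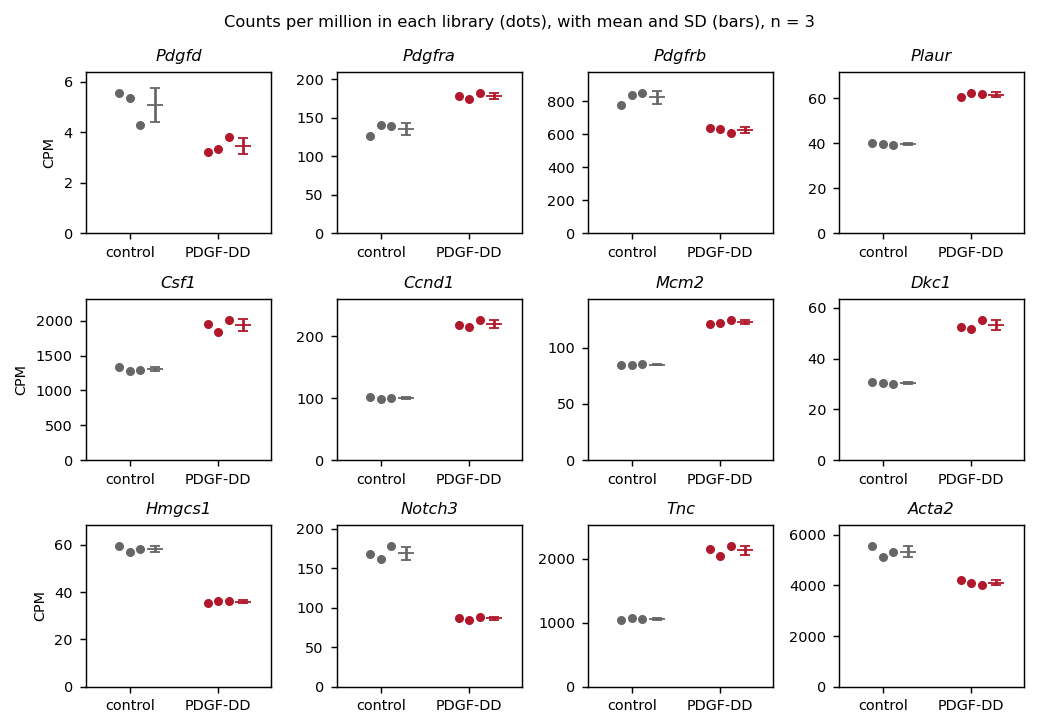
Expression of 12 genes in each library (dots, CPM, vertical axes starting at 0) for the control and PDGF-DD groups, with the mean and SD beside them (n = 3 per group). Pdgfra, Plaur, Csf1, Ccnd1, Mcm2, Dkc1 and Tnc are higher with PDGF-DD in each library than in any control library, and Pdgfd, Pdgfrb, Hmgcs1, Notch3 and Acta2 are lower.

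Genes downstream of growth-factor signalling through the ERK kinase pathway rose. Of 19 tested feedback and output genes of this pathway, 15 rose and 1 fell (16 and 2 adjusted over the list alone), with a median log2 fold change of 0.41 (camera adjusted p = 8.46e-08, and adjusted p = 0.259 with an estimated correlation). Ccnd1, which encodes cyclin D1, rose from 101 ± 1.48 to 220 ± 6.13 CPM (log2 fold change 1.13, SE 0.04, edgeR adjusted p = 4.49e-17). The phosphatase gene Dusp4, the transcription factor gene Etv4 and Phlda1 rose by log2 fold changes of 0.83, 0.96 and 0.97. The member that fell was Spry1, an inhibitor of receptor tyrosine kinase signalling and the most abundant member of the list, from 329 ± 15.9 to 244 ± 11.2 CPM. Of 24 immediate early genes, 11 rose and 3 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0246, and adjusted p = 0.274 with an estimated correlation). Fosl1 and Egr2 rose most, Myc rose from 88.2 ± 4.00 to 124 ± 1.8 CPM, and Klf4 fell from 81.2 ± 5.14 to 55.7 ± 2.36 CPM. Of the immediate early genes 6 fell under upper-quartile scaling and 1 without PDGF-DD replicate 2.

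Genes that FoxO transcription factors activate mostly fell: 12 of 18 were lower and 3 higher, with the same numbers adjusted over the list alone and a median log2 fold change of -0.33 (camera adjusted p = 0.00427, and adjusted p = 0.274 with an estimated correlation). Klf2 fell from 54.4 ± 4.43 to 32.8 ± 0.75 CPM, Ccng2, a cyclin associated with arrest, fell by a log2 fold change of -0.56 and the selenium transporter gene Selenop by -0.34. Against this direction, the pseudokinase gene Trib2 rose from 42.2 ± 0.54 to 67.5 ± 3.77 CPM and Txnip rose by a log2 fold change of 0.17.

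Genes of DNA replication rose. Of 48 genes of the G1/S phase of the cell cycle, 45 rose and none fell (48 and 0 adjusted over the list alone), with a median log2 fold change of 0.53 (camera adjusted p = 6.69e-22, and adjusted p = 0.23 with an estimated correlation). The ribonucleotide reductase subunit gene Rrm2 rose from 76.5 ± 3.50 to 125 ± 4.68 CPM and Uhrf1, needed for maintenance of DNA methylation, from 68.5 ± 1.38 to 107 ± 5.75 CPM. The replicative helicase subunit genes Mcm4, Mcm2 and Mcm6 rose by log2 fold changes of 0.58, 0.53 and 0.50. Genes of G2 and mitosis had a smaller median change: 34 of 56 rose and none fell (36 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.21 (camera adjusted p = 2.56e-08, and adjusted p = 0.259 with an estimated correlation). Cdk1, the mitotic kinase, rose by a log2 fold change of 0.38 and Top2a, which untangles replicated chromosomes, by 0.35. Under upper-quartile scaling 31 of these genes rose and 1 fell.

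Genes of ribosome production, many of them MYC targets, also rose. Of 38 genes, 37 rose and none fell, with the same numbers adjusted over the list alone and a median log2 fold change of 0.43 (camera adjusted p = 5.46e-19, and adjusted p = 0.201 with an estimated correlation). Dkc1, the pseudouridine synthase of ribosomal RNA, rose from 30.4 ± 0.41 to 53.2 ± 1.87 CPM (log2 fold change 0.81, SE 0.05, edgeR adjusted p = 5.23e-12). The nucleolar protein genes Nop56, Nolc1 and Ncl rose by log2 fold changes of 0.57, 0.53 and 0.40. Chaperones of the endoplasmic reticulum and other unfolded protein response genes rose as a list: 11 of 20 rose and 2 fell (13 and 3 adjusted over the list alone), with a median log2 fold change of 0.12 (camera adjusted p = 0.00893, and adjusted p = 0.259 with an estimated correlation). The number that fell was 4 without control replicate 1, and 1 under total count scaling and without control replicate 2 or 3 or PDGF-DD replicate 1 or 3. The chaperone genes Hyou1 and Hspa5 rose by 0.34 and 0.24 on the log2 scale.

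Genes of cholesterol synthesis fell together. Of 31 targets of the sterol-regulated transcription factor SREBP2 and related lipid genes, 23 fell and 2 rose (24 and 2 adjusted over the list alone), with a median log2 fold change of -0.40 (camera adjusted p = 2.56e-08, and adjusted p = 0.201 with an estimated correlation). Hmgcs1, an early enzyme of the mevalonate pathway, fell from 58.2 ± 1.2 to 35.9 ± 0.56 CPM (log2 fold change -0.70, SE 0.05, edgeR adjusted p = 2.97e-11). The sterol oxidase gene Msmo1 fell by a log2 fold change of -0.69 and Srebf2 itself by -0.58. The members that rose were genes of fatty acid synthesis: Fasn, the fatty acid synthase, from 195 ± 4.85 to 224 ± 4.22 CPM, and Acaca, named after its value was seen, from 62.0 ± 2.94 to 72.7 ± 2.14 CPM. Not all fatty acid genes of the list rose, as the desaturase gene Scd2 fell by a log2 fold change of -0.22 (edgeR adjusted p = 0.000157).

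Genes of glycolysis and hypoxia response went both ways, with 15 of 32 higher and 4 lower (16 and 6 adjusted over the list alone). The list did not stand apart (camera adjusted p = 0.0502, and adjusted p = 0.274 with an estimated correlation), although it did without control replicate 3 (0.0403), without PDGF-DD replicate 3 (0.0418) and without the low-count filter (0.0274), and by fry it was higher (adjusted p = 0.00236). Without control replicate 2, PDGF-DD replicate 1 or PDGF-DD replicate 3, 2 of its genes fell. The glucose transporter gene Slc2a1 and the lactate transporter gene Slc16a3 rose by log2 fold changes of 0.35 and 0.34, Ldha rose by 0.26 and Ndrg1 fell by 0.52. In the list of serine synthesis, amino acid transport and ATF4 targets, 11 of 31 rose and 5 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.182, and adjusted p = 0.365 with an estimated correlation), and by fry the list was higher (adjusted p = 0.00612). Without PDGF-DD replicate 1 or 3, 3 of these genes fell. Psat1, an enzyme of serine synthesis, rose from 97.8 ± 4.86 to 176 ± 1.28 CPM (log2 fold change 0.85, SE 0.04, edgeR adjusted p = 3.09e-14), while Atf4 itself stood at 382 ± 4.80 and 386 ± 4.52 CPM and did not pass.

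Fibroblast matrix genes changed in both directions, with more falling than rising. Of 32 genes of fibrillar collagens and their assembly, 20 fell and 6 rose, with the same numbers adjusted over the list alone and a median log2 fold change of -0.14 (camera adjusted p = 0.0186, and adjusted p = 0.399 with an estimated correlation). Col1a1, the most abundant of them, fell from 20773 ± 483 to 17880 ± 525 CPM (log2 fold change -0.22, SE 0.03, edgeR adjusted p = 7.05e-06), and the collagen lysyl hydroxylase gene Plod2 fell by a log2 fold change of -0.43. Col15a1 rose from 244 ± 11.3 to 410 ± 9.99 CPM, and Col5a3 and the procollagen peptidase gene Adamts14 rose by log2 fold changes of 0.72 and 0.59. Of 40 matrix glycoproteins and proteoglycans 21 fell and 5 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.00281, and adjusted p = 0.274 with an estimated correlation). Fibronectin (Fn1) fell from 18297 ± 1110 to 15220 ± 180 CPM, and elastin (Eln), thrombospondin 2 (Thbs2) and osteoglycin (Ogn) fell by log2 fold changes of -0.44, -0.49 and -0.58. Tenascin C (Tnc), a matrix protein of wound repair, rose 2.00-fold, from 1065 ± 15.7 to 2128 ± 75.8 CPM (log2 fold change 1.00, SE 0.04, edgeR adjusted p = 7.3e-17).

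Of 27 matrix proteases and their inhibitors 7 rose and 13 fell, with the same numbers adjusted over the list alone. The list did not stand apart from other genes (camera adjusted p = 0.114, and adjusted p = 0.399 with an estimated correlation), but on balance its members were lower, with a median log2 fold change of -0.22 (-0.07 without PDGF-DD replicate 1; fry adjusted p = 0.00732). Timp1, an inhibitor of matrix metalloproteinases, rose from 746 ± 82.0 to 1391 ± 48.4 CPM, and the related inhibitor Timp2 fell from 1534 ± 29.9 to 1259 ± 28 CPM. The aggrecanase gene Adamts5 fell by a log2 fold change of -0.64 and the metalloproteinase gene Mmp11 by -0.69, and Mmp10 rose by 1.07 and Adam12 by 0.44.

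Contractile and myofibroblast genes fell. Of 26 genes 19 fell and none rose, with the same numbers adjusted over the list alone and a median log2 fold change of -0.24 (camera adjusted p = 6.22e-07, and adjusted p = 0.259 with an estimated correlation). Smooth muscle actin (Acta2), the usual marker of myofibroblasts, fell from 5327 ± 209 to 4108 ± 101 CPM (log2 fold change -0.37, SE 0.04, edgeR adjusted p = 5.4e-09). Smooth muscle myosin heavy chain (Myh11) fell from 24.5 ± 1.3 to 12.0 ± 1.59 CPM, integrin α8 (Itga8) from 37.5 ± 0.98 to 19.4 ± 1.53 CPM and the myosin light chain gene Myl9 from 344 ± 16.4 to 230 ± 10.1 CPM. Markers of smooth muscle cells and pericytes moved in the same direction: 6 of 9 fell and 1 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.00427, and adjusted p = 0.274 with an estimated correlation). Among them Notch3, a receptor of vascular mural cells, fell from 169 ± 8.21 to 86.6 ± 1.57 CPM and Lmod1 by a log2 fold change of -0.70. The member that rose, named after its value was seen, was Cspg4, by 0.24.

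Genes that TGF-β regulates did not move together, with 7 of 27 higher and 11 lower (8 and 13 adjusted over the list alone), and the list did not stand apart (camera adjusted p = 0.518, and adjusted p = 0.803 with an estimated correlation; fry adjusted p = 0.887). Without PDGF-DD replicate 3, 8 were higher and 7 lower. The latent TGF-β binding protein gene Ltbp1 rose from 42.9 ± 0.14 to 86.3 ± 4.86 CPM, while the ligand gene Tgfb2 fell from 117 ± 6.89 to 60.7 ± 2.58 CPM and the integrin gene Itgb5 fell by a log2 fold change of -0.51. Of 22 targets of the mechanosensitive YAP/TEAD factors 7 rose and 10 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.568, and adjusted p = 0.803 with an estimated correlation), and by fry the list was lower (adjusted p = 0.0372). Their median, -0.003 on the log2 scale, turned positive under total count scaling and without control replicate 2 or 3 or PDGF-DD replicate 2 or 3. Ccn2, known as connective tissue growth factor, rose from 2608 ± 68.1 to 3046 ± 70.6 CPM, and Ankrd1 rose by a log2 fold change of 0.33. Of 17 genes of the BMP pathway and its Id targets 5 rose and 6 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.713, and adjusted p = 0.822 with an estimated correlation; fry adjusted p = 0.0505), and the list's median (-0.06) and mean (0.10) differed in sign, the median being 0.10 without control replicate 1, 0.01 without control replicate 3 and 0.04 without PDGF-DD replicate 1. Without PDGF-DD replicate 3, 2 of these genes rose and 5 fell. Bmp4 and Id4 fell by log2 fold changes of -0.86 and -0.89.

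Genes of quiescent and progenitor fibroblasts fell, 12 of 25 being lower and 2 higher (13 and 2 adjusted over the list alone), with a median log2 fold change of -0.20 (camera adjusted p = 0.00111, and adjusted p = 0.259 with an estimated correlation). Tcf21, a transcription factor of resident cardiac fibroblasts, fell from 131 ± 4.60 to 86.4 ± 2.50 CPM, and Gas6, a ligand of the receptor AXL, from 164 ± 4.29 to 96.1 ± 4.62 CPM. General fibroblast markers did not stand apart, with 4 of 20 higher and 9 lower and the same numbers adjusted over the list alone (camera adjusted p = 0.141, and adjusted p = 0.399 with an estimated correlation), and by fry they were lower (adjusted p = 0.00365).

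**Figure D3:**
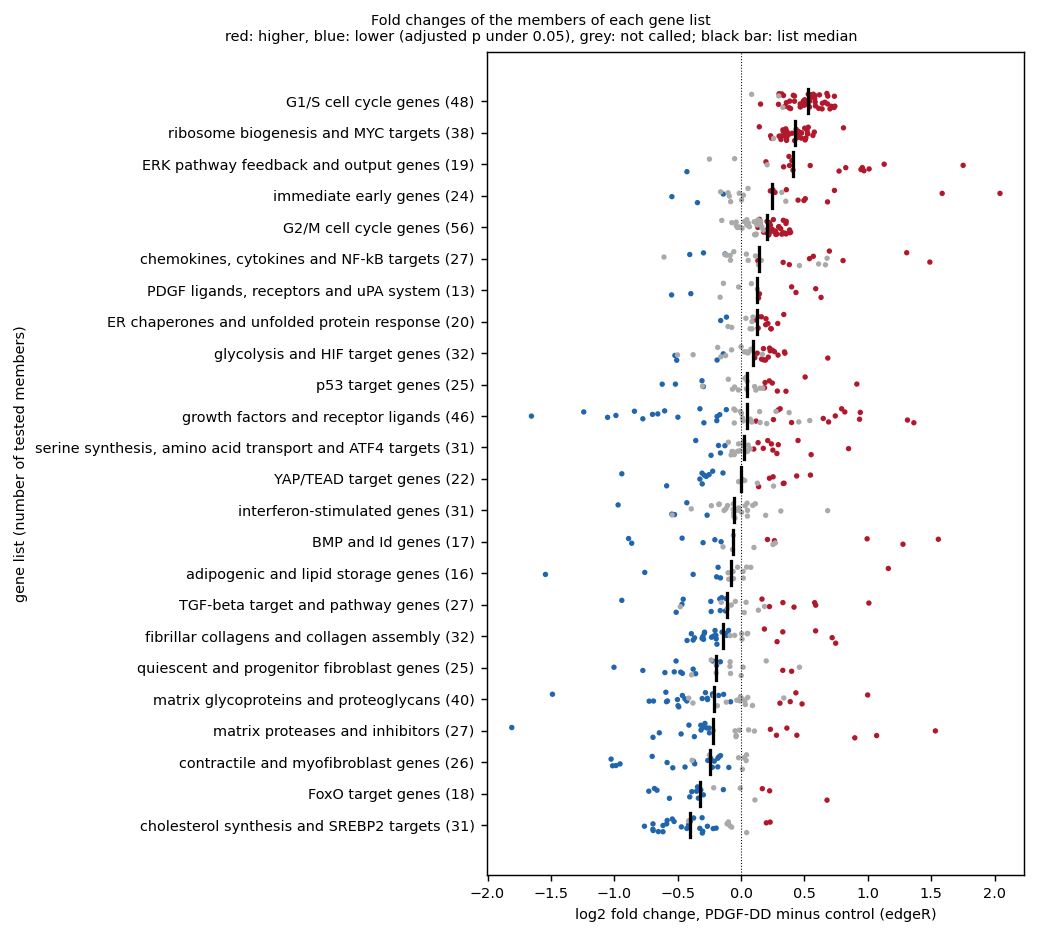
Log2 fold changes (horizontal axis, PDGF-DD minus control, edgeR, 3 libraries per group) of the members of each gene list of a pathway or function. Each dot is a gene, red when higher and blue when lower at an adjusted p under 0.05 and grey otherwise, and black bars are list medians. The medians range from -0.40 for cholesterol synthesis to 0.53 for G1/S genes.

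Among secreted signals, chemokines, cytokines and NF-κB targets rose as a list, with 9 of 27 higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.0481, and adjusted p = 0.368 with an estimated correlation). The list no longer passed without control replicate 2 (0.0762) or without PDGF-DD replicate 3 (0.124), the lowest camera adjusted p under any alternative being 0.0176, without control replicate 1. By fry the list was higher (adjusted p = 0.0127). The macrophage growth factor Csf1 rose from 1304 ± 29.9 to 1936 ± 89.0 CPM (log2 fold change 0.57, SE 0.04, edgeR adjusted p = 9.93e-12), and the cytokine genes Lif and Cxcl12 rose by log2 fold changes of 0.54 and 0.38. Growth factors and receptor ligands went both ways, 14 of 46 rising and 16 falling (15 and 16 adjusted over the list alone; camera adjusted p = 0.518, and adjusted p = 0.611 with an estimated correlation; fry adjusted p = 0.053). Dkk2, a modulator of Wnt signalling, and Igfbp3 rose by log2 fold changes of 1.31 and 0.69, and Vegfd fell by 0.70.

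No interferon-stimulated gene rose and 5 of 31 fell, with the same numbers adjusted over the list alone, while 1 rose and 4 fell without control replicate 1 and 3 rose and 4 fell without PDGF-DD replicate 2. That list did not stand apart (camera adjusted p = 0.141, and adjusted p = 0.436 with an estimated correlation), except without control replicate 3 (0.0398), and by fry it was lower (adjusted p = 0.0412). Gbp2, an interferon-induced GTPase, was 1.96-fold lower. In the p53 target list 8 of 25 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.135, and adjusted p = 0.274 with an estimated correlation; higher by fry, adjusted p = 0.00384), Plk2 rising from 71.7 ± 1.49 to 135 ± 5.88 CPM and Cdkn1a by a log2 fold change of 0.19. Without PDGF-DD replicate 3, 2 of the p53 targets fell. Of 16 adipogenic and lipid storage genes 6 fell and 1 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.141, and adjusted p = 0.274 with an estimated correlation), and by fry the list was lower (adjusted p = 0.00612). The gene that rose was Angptl4, an inhibitor of lipoprotein lipase, from 34.6 ± 2.52 to 77.4 ± 4.17 CPM.

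Among markers of other cardiac cell types, those of Schwann and neural crest cells stood apart as lower by camera, besides the mural markers above. Of 9 genes, 3 fell and none rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0327, and adjusted p = 0.259 with an estimated correlation). The call was lost without control replicate 3 (0.0536), the lowest camera adjusted p under any alternative being 0.014 with the replicate block. By fry the list was lower (adjusted p = 0.00732). None of its genes fell without control replicate 3 or PDGF-DD replicate 1, and 1 fell without PDGF-DD replicate 3. The list summed to between 39.5 and 49.2 CPM per library. Cardiomyocyte markers (4 of 13 lower, 1 higher; camera adjusted p = 0.0838, and adjusted p = 0.274 with an estimated correlation) passed without control replicate 3 (0.0403), without PDGF-DD replicate 3 (0.0324) and with the replicate number as a block (0.0335), and by fry they were lower (adjusted p = 0.0103). The number of these markers that fell was 2 under total count scaling and without control replicate 1 or 2 or PDGF-DD replicate 2 or 3. Of these Tnnt2, cardiac troponin T, fell from 156 ± 5.20 to 115 ± 8.94 CPM. Macrophage and leukocyte markers (3 of 19 lower, 0 higher; 2 lower adjusted over the list alone; camera adjusted p = 0.105, and adjusted p = 0.368 with an estimated correlation) passed without either of the same libraries (0.0403 each), and by fry they were lower (adjusted p = 0.0276). Of these markers 5 fell without control replicate 3 and 1 without PDGF-DD replicate 1 or 2. Lysozyme (Lyz2, which has a near-identical neighbour) fell from 139 ± 9.80 to 121 ± 1.38 CPM.

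Endothelial markers did not stand apart (2 of 16 lower, 1 higher; camera adjusted p = 0.298, and adjusted p = 0.414 with an estimated correlation; fry adjusted p = 0.0704), nor did epicardial and mesothelial markers (3 of 13 lower, 1 higher, and 4 lower, 1 higher adjusted over the list alone; camera adjusted p = 0.311, and adjusted p = 0.399 with an estimated correlation), although by fry the latter were lower (adjusted p = 0.0144). Of the endothelial markers 4 fell without control replicate 1, and 1 without control replicate 3 or PDGF-DD replicate 1 or 3. No epicardial or mesothelial marker rose without control replicate 2. The counts of cardiomyocyte and endothelial markers were the same adjusted over the list alone. The angiopoietin receptor gene Tek fell by a log2 fold change of -0.53 and the VEGF receptor gene Flt1 rose by 0.26. Erythroid and lymphoid markers were too low to test, summing to at most 0.654 CPM per library. As for RNA quality, 3 of 6 tested replication-dependent histone genes fell (2 fell and 1 rose without control replicate 1), with the same number adjusted over the list alone (camera adjusted p = 0.195, and adjusted p = 0.408 with an estimated correlation; lower by fry, adjusted p = 0.0412), and the 10 most abundant genes held between 9.79% and 10.7% of the counts. The fall of these histone genes was opposite in direction to the rise of the G1/S genes above, and its cause was not tested. None of the 4 tested sex-linked genes differed by the test (edgeR). The Y-linked gene Ddx3y stood at 47.8 ± 1.37 CPM in control and 48.7 ± 0.48 CPM with PDGF-DD. None of the 13 mitochondrially encoded genes of the list was matched to a gene in the deposited values, so they could not be analysed.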

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

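All alternatives here were planned before the data were examined. No called gene changed direction under any of the 16 other fits that tested it, and between 77.5% (DESeq2) and 99.7% (size factors) of the 4845 calls were made again in the same direction. With 1 library left out, 2147 to 2643 genes were higher and 1729 to 2374 lower. DESeq2 gave 2042 and 1726 (515 genes had no adjusted p), limma on log2(FPKM + 1) 2505 and 1787, and upper-quartile scaling 2244 and 2636, the only scaling tried with more falls than rises. Requiring a log2 fold change of at least 1 left 54 higher and 108 lower, since most changes were small. The replicate numbers did not pair the libraries, as the deviations of same-numbered libraries correlated at -0.0661, -0.0911 and -0.0257; with the replicate block 2269 genes were higher and 2076 lower. Pdgfd stayed lower, with log2 fold changes between -0.65 and -0.30 and adjusted p between 0.000592 and 0.0205 where it was tested. The value of -0.30 came from limma on log2(FPKM + 1), where the added 1 shrinks the change of a gene at a low level. With log2(FPKM + 0.1) the value was -0.48. The filter of 5 CPM removed Pdgfd.

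Of the lists of pathways and functions, 7 were higher and 6 lower by camera; with an estimated correlation these numbers were 0 and 0, and with fry, which does not compare a list with other genes, 11 and 10. Of the other lists, which hold markers of other cell types, fibroblast markers and signs of RNA quality, 2 were lower; the number was 0 with an estimated correlation, 7 with fry and 2 to 4 with 1 library left out, 4 being without PDGF-DD replicate 3. The correlation was estimated from 6 libraries with 4 residual degrees of freedom. The cause of the differences was otherwise not tested. Depth limits mainly genes of a few CPM, such as Pdgfd.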

Other observations

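The groups of genes that follow, and the genes named with them, were chosen after the data were seen. Gene families with a shared symbol stem were examined where at least 10 members were tested, 162 families in all. By camera 17 were higher and 6 lower, and none of these calls held with an estimated correlation. The median of each family named kept its sign under the 3 other scalings. Genes of RNA helicases (Ddx) rose in 23 of 33 cases and fell in none (camera adjusted p = 4.3e-05, and adjusted p = 0.559 with an estimated correlation). Nuclear pore genes (Nup) rose in 16 of 20 cases with a median log2 fold change of 0.24, with Nup107 rising by 0.46 and Nup85 by 0.46, and fell in 1. Translation initiation factors (Eif) rose in 28 of 54 cases, RNA polymerase subunits (Polr) in 17 of 28, regulatory subunits of the proteasome (Psmd) in 11 of 14 and proteins of the mitochondrial ribosome (Mrpl and Mrps) in 15 of 49 and 14 of 29. In Eif and Psmd 1 member each fell. The camera adjusted p of these families lay between 4.79e-05 for Nup and 0.00713 for Mrps, and with an estimated correlation their adjusted p lay between 0.559 and 0.812. Related families did not stand apart. Of the cytosolic ribosomal proteins, Rpl rose in 1 of 50 cases (camera adjusted p = 0.878) and Rps in 2 of 43 (camera adjusted p = 0.965). Core subunits of the proteasome (Psmb) rose in 1 of 10 (camera adjusted p = 0.403).

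Lipid transporters of the ABCA family fell in 8 of 10 cases, with a median log2 fold change of -0.38 (camera adjusted p = 0.00411, and adjusted p = 0.559 with an estimated correlation), among them Abca6 from 5.74 to 2.07 CPM and Abca9 from 12.2 to 7.70 CPM. The cholesterol exporter gene Abca1 rose from 35.3 to 39.8 CPM (edgeR adjusted p = 0.0172), a call lost in DESeq2, in limma on the FPKM values and without control replicate 1, control replicate 3 or PDGF-DD replicate 3 (adjusted p from 0.0548 to 0.0952). Kruppel-like factors (Klf) fell in 8 of 14 cases and rose in 2 (camera adjusted p = 0.0432, and adjusted p = 0.726 with an estimated correlation). Serpinb2, a serpin that inhibits uPA, rose from 0.46 to 5.89 CPM (log2 fold change 3.67, SE 0.20, edgeR adjusted p = 1.44e-13), and Ereg, a ligand of the EGF receptor, rose from 53.7 to 94.7 CPM.

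In the tests that follow, the bound for the loss of the whole Pdgfd gene, the limits on high-level mural markers and the interval of the LXR median were chosen after the results were seen. The 4845 genes called between the groups compare with at most 0 in the other 9 of the 10 splits of the 6 libraries into 3 and 3. Each of those 9 splits mixes control and PDGF-DD libraries within its groups, which widens the spread there. Their numbers therefore do not show how many calls would arise with no difference between the groups. In 1 of the 10 splits, the real one, the number was as large, and 10 splits are too few for a share under 0.05.

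The cholesterol synthesis genes were lower with PDGF-DD, with a median log2 fold change of -0.40. Under the 3 other scalings the median closest to 0 was -0.3891, so the fall does not hinge on the choice among them. These scalings differed too little from TMM to test scaling as the cause. The median log2 fold change of all tested genes lay between -0.0315 (upper quartile) and -0.000458 (total count) under them. A trend with transcript length or GC content is argued against as the whole cause, since the median was -0.3582 after such a trend was subtracted. A candidate explanation is a sterol surplus in the treated cells, which would raise targets of the sterol-sensing LXR receptors: the 12 tested targets had a median log2 fold change of -0.1676 (96.1% interval from -0.35 to 0.02), 2 rose (Abca1, and Arl4c with a call lost without PDGF-DD replicate 2, adjusted p = 0.0502) and 5 fell. A median at or below 0, or at least as many falls as rises, had been set beforehand as the bound against this explanation, and the values met it. The interval, added after the results were seen, includes 0 and the members went both ways, so by this later rule the explanation stays open. The treatment itself and the genotype that the labels attach to it were not separated.

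The contractile genes and the markers of smooth muscle cells and pericytes were both lower with PDGF-DD. Under the 3 other scalings the median of the contractile list was -0.2330 at the least, but these differed too little from TMM to test scaling as the cause. A trend with transcript length or GC content is argued against as the whole cause, with a median of -0.2097 after correction. A lower share of mural cells in the treated cultures may also lower these genes. Of 8 mural markers that are not fibroblast markers, 2 of them also contractile genes, 2 had a 95% lower limit above -0.2, which had been set as the bound against this explanation. These were Cspg4 and Mcam at 118 and 105 CPM, levels that may hide the loss of a small share if fibroblasts express them too. Notch3 fell at a similar level (128 CPM), so level alone does not set Cspg4 and Mcam aside, and the markers do not decide the question. Myh11 (-1.02) and Notch3 (-0.97) fell, as did Rgs5 (-0.48), whose call was lost in limma on the FPKM values and without control replicate 2, control replicate 3 or PDGF-DD replicate 3 (adjusted p from 0.064 to 0.12), and a change of share and a change within fibroblasts cannot be told apart, since the fibroblasts may express the same genes.

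Reads of Pdgfd were present in all libraries and fewer with PDGF-DD. A difference of genotype between the groups with the whole gene lost is argued against by the lower 95% limit of the log2 fold change, -0.8299, because such a loss would leave almost no reads. A difference of genotype with sequence from another strain around the edited locus could change neighbouring genes. Of the 20 nearest tested genes 9 were called (45%, against 36.5% of all tested genes; one-sided exact hypergeometric p = 0.284), with Mmp13 (1.53) and Mmp10 (1.07) moving most, so this cannot be told apart from the treatment with the 20 genes at hand. A loss of single exons of Pdgfd was not tested, as the deposited counts are per gene.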
